A study of Mus musculus with 8 samples.

How the data were processed

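White adipose tissue was taken from 5-week-old mice of a mixed 129 × C57BL/6 strain on regular chow, per the labels. Of the 8 samples, 4 were wild type (WT) and 4 came from mice called Ad/NICD, in which the intracellular domain of Notch1, the active part of the receptor, was overexpressed. The labels call the samples biological replicates. The fat depot, the sex of the mice and the promoter behind the transgene are not given in the sources used here.

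Total RNA was labelled with Cy3 or Cy5 and hybridised to 4 arrays with 2 colours each. Per the submitters' processing notes, the scans were read with Agilent Feature Extraction 11.5. The deposited scanner tables hold intensity values for each spot, as median foreground, median background, background-subtracted and processed signals, with no between-array normalisation. The deposited tables also hold a log10 ratio of the red over the green processed signal, which matched the 2 processed signals to within 0.00714 where both were above 50. A deposited table of the authors' values is on a log2 scale. Each of its columns equalled the log2 processed signal of 1 channel of the same-numbered array minus a constant, with the 75th percentile of each column at 0. Column medians lay between -3.84 and -3.52. The scale and centring of this table are thus known from the values, and no step behind them is given in the sources used here.

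The scanner tables of WT and Ad/NICD samples with the same replicate number were identical, so each array carried 1 WT and 1 Ad/NICD sample. No array had its dyes swapped, and dye and genotype cannot be told apart. The sources conflict on which dye marked which genotype. The dye tag of each sample gives Cy5 for the 4 WT samples and Cy3 for the 4 Ad/NICD samples. The labelling protocol gives Cy3 to controls and Cy5 to test samples, without naming genotypes. In the authors' value table, the 4 WT columns held the green (Cy3) channel and the 4 Ad/NICD columns held the red (Cy5) channel. Red over green was therefore taken as Ad/NICD over WT, as the likely direction. The direction written down before the data were examined followed the dye tags, and was replaced for this reason. If the dye tags were right, every sign would turn, while sizes, counts and p-values would stay, and levels given for WT and Ad/NICD samples would change places.

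Background was corrected with normexp (offset 50) on the median foreground and median background, because the tables hold no mean foreground. Each array was then normalised by loess with control spots at weight 0 (limma 3.58.1 in R 4.3.3). Spots of 1 probe were averaged. Of 55681 probes that are not controls, 28026 were matched through their accession to a gene symbol in a RefSeq table of the GRCm38.p6 assembly, used for names only, and 27655 kept the name in the files. Probes were kept when well above background in at least 1 channel on at least 3 of the 4 arrays. The array of replicate 1 has no such flags. They were rebuilt from the background-subtracted signal and the spread of the negative controls, a rule that gave the scanner's own flag for 96.4% to 99.7% of spots on the other 3 arrays. The brightest kept probe stood for each gene name, which left 24633 gene names, 15627 of them with a RefSeq symbol.

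The 4 log2 ratios of each gene were tested against 0 with limma (lmFit and eBayes), with Benjamini-Hochberg adjustment and a threshold of 0.05. This is the paired fit, with the array as the pair. The correlation between same-numbered samples, as deviations from their group means, was 0.17, 0.17, 0.57 and 0.53 for replicates 1 to 4. The samples of a pair share an array, and every pair lay above 0.1. What else a pair shares is not given in the labels, and the correlations alone do not show what they come from. For replicate 1 a sample of another number correlated more strongly, at 0.29. Levels per sample are log2 signals of each channel after loess and quantile scaling of average brightness between arrays.

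The lists of genes tested numbered 30, fixed before the data were examined: Notch targets, Notch pathway, adipocyte, lipogenesis, lipolysis, fatty acid oxidation, thermogenic, respiratory chain, insulin and glucose, cholesterol, progenitor, extracellular matrix, cell cycle, p53 and senescence, ER stress, immediate early, inflammatory, macrophage, T cell, B cell, granulocyte and mast cell, endothelial, smooth muscle, skeletal muscle, mammary epithelium, mesothelium, epididymis, erythroid, nerve and sex-linked genes. Of their 492 genes, 464 were measured. They were tested with limma's camera at a preset correlation of 0.01, and again with camera at an estimated correlation and with fry. Camera asks whether a list differs from the other genes. With the array as a random block, its preranked form was run on that fit's statistics, and the trend setting was passed to it without the robust one.

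The genes named were chosen by a rule fixed before the data were examined. It takes genes past the threshold with the same sign on all 4 arrays and a real symbol, as the 6 largest rises and the 6 largest falls, then up to 4 past the threshold from the Notch target, adipocyte, lipogenesis and thermogenic lists and up to 2 from each other list. Notch1, Hes1, Hey1, Heyl, Nrarp, Adipoq, Lep, Pparg, Ucp1 and Prdm16 are given whatever their values. Anxa2, and the examples from lists, which come from the 3 members with the lowest p or are members that passed with the array as a random block, were chosen after their values were seen. An example from 1 list is not reported here. Probes were compared for the genes chosen by the rule, Anxa2 and the list examples with the lowest p. Different probes of 1 such gene pointed the same way, except for 1 probe of Kdr, though sizes differed. For the other genes named below, probes were not compared.

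The fit was tested on simulated arrays of the Ad/NICD against WT comparison with 24633 genes, the measured spread of each gene and an added dye curve. It called 75 of 100 genes changed by a log2 value of 1, and 88 of 100 changed by a log2 value of 2. Of all its calls, 5.17% were unchanged genes. The simulated errors were independent between genes, and the changed genes were drawn at random with the same shift on all arrays. These rates need not hold for genes that changed in the measured data. A list shifted by 0.5 was called at the preset correlation and missed at the estimated one, and 1 unshifted list was called at the preset correlation.

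Alternatives covered the background correction, the scanner's processed signals, the normexp offset, median centring, scaling between arrays, the filter on dim probes, the choice among probes of a gene, separate-channel fits without and with the array as a random block, eBayes with trend and robust settings, the authors' values, a plain test of each gene's 4 ratios, and leaving out each replicate. An exact permutation test used SciPy 1.17.1, and plots were drawn with matplotlib 3.10.9. Control spots were left out of all tests.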

Results

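Gene expression in white adipose tissue was measured on 2-colour arrays in 4 WT mice and 4 Ad/NICD mice, which overexpress the Notch1 intracellular domain. Each of the 4 arrays carried 1 sample of each genotype. Median foreground in the green channel was between 72 and 88.5 intensity units over a background of 45 to 46. In the red channel it was between 34 and 43.5 over 19 to 20. Between 58.1% and 68.6% of spots were well above background in a channel, and the number of arrays limits the precision.

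The comparison asked which transcripts differ in white adipose tissue when the Notch1 intracellular domain is overexpressed. Signs are for Ad/NICD over WT in the likely direction, with red (Cy5) as Ad/NICD, as the authors' value table has it. The labelling protocol, which names no genotypes, has it so too if WT is the control. The dye tags of the samples say the opposite, which would turn every sign and swap the genotype named for each sample's level. Without a dye swap, a dye bias of a single probe cannot be told apart from genotype.

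Heyl, a transcription factor and known target of Notch signalling, rose by a log2 ratio of 2.87 ± 0.17 (SE, n = 4 arrays), a fold of 7.33, with an adjusted p of 0.0406 in limma. It was higher on 4 of 4 arrays, with a mean log2 signal of 8.69 ± 0.087 in WT and 11.56 ± 0.43 in Ad/NICD (SD, n = 4). Akr1cl, an aldo-keto reductase family member, rose by 3.33 ± 0.21. Gdf5, a growth factor of the bone morphogenetic protein (BMP) family, rose by 2.48 ± 0.10 on its brightest probe, with 0.67 on its other probe. That other Gdf5 probe was dim, at a mean log2 signal of 6.65 against 9.30, and the offset of 50 pulls ratios of dim probes toward 0. Among the genes that fell, B3galt2, a galactosyltransferase, had a log2 ratio of -2.77 ± 0.18, and Acvr1c, the activin receptor-like kinase ALK7 found in adipocytes, had -1.71 ± 0.11.

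In all, 13 of 24633 gene names passed the threshold, 7 higher and 6 lower. The other rises were Grb14, an adaptor that binds the insulin receptor, at 1.17 ± 0.070, Gdf7, another growth factor of the BMP family, at 1.02 ± 0.061, Zfp949 at 1.01 ± 0.067 and Anxa2, a calcium-dependent membrane-binding protein, at 0.94 ± 0.064. The other falls were Cdsn, a protein of cornified-cell junctions, at -2.20 ± 0.14, Slc13a4, a sulfate transporter, at -1.98 ± 0.15, Bnip3, a mitochondrial protein of mitophagy, at -1.52 ± 0.11, and Bmp3 at -1.14 ± 0.079. Of the 13, 12 changed by 2-fold or more, 6 in each direction. Each had the same sign on 4 of 4 arrays, and adjusted p-values ran from 0.0302 for Gdf5 to 0.0483 for Slc13a4. Over all gene names, a mean of 2-fold or more with the same sign on all 4 arrays was found for 49 higher and 143 lower. Most of these did not pass the threshold.

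An unadjusted p under 0.05 was found for 3784 gene names, where chance gives 1232. The count of calls was fragile: it was 0 without replicate 1, 2 or 3, 43 without replicate 4 (9 higher, 34 lower), and 0 with eBayes trend and robust settings. Replicate 4 is the 1 pair with the male pattern of sex-linked genes, given below. The fit over all arrays thus mixes pairs of both sexes by these markers. Separate channels without the replicate block gave 257 genes, and the array as a random block gave 495, with 12 of the 13 genes among both sets. List members are given for the ratio fit, and those that pass over all genes with the array as a random block are named beside it.

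**Figure D1:**
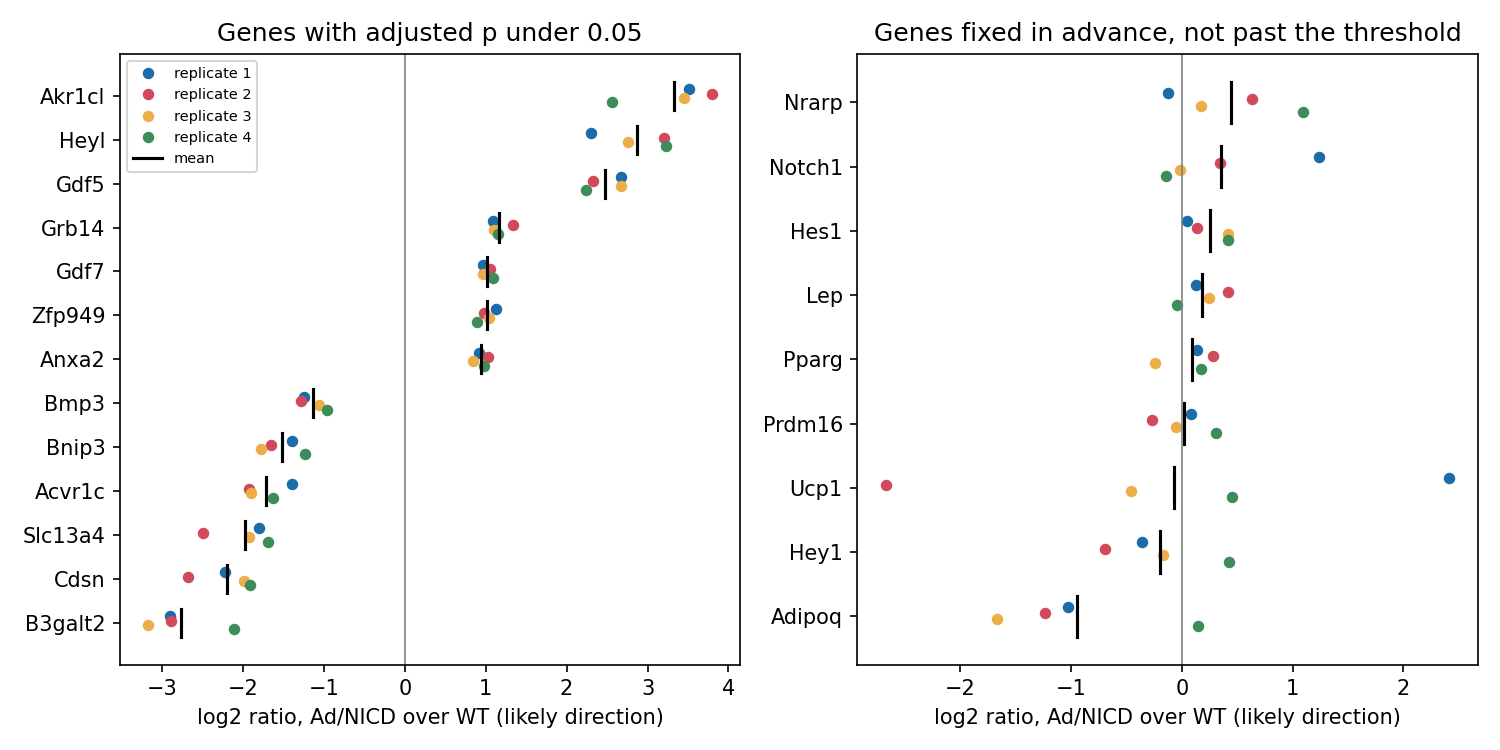
Log2 ratios of Ad/NICD over WT (horizontal axis, likely direction) for single genes, with 1 coloured point for each of the 4 arrays and a black line at the mean. The 13 genes past the threshold are on the left, from Akr1cl at 3.33 to B3galt2 at -2.77, and the genes fixed in advance that did not pass are on the right, where Ucp1 spans 2.42 to -2.67.

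Genes of the Notch pathway differed in their values. Heyl was the sole Notch target past the threshold over all genes, and 2 of 12 measured targets were higher when adjusted over the list alone, Heyl and Notch3. Notch3, a receptor that is itself induced by Notch signalling in some cells, had 0.73 ± 0.16, Nrarp 0.44 ± 0.21, Hes1 0.26 ± 0.091 and Hey1 -0.20 ± 0.18, and none of these passed over all genes. Hes1 and Nrarp were dim, at mean log2 signals of 6.39 and 6.63 in WT. Y-linked genes, mostly below background in replicates 1 to 3, had medians of 5.85 to 5.89 there. The normexp offset of 50 pulls ratios of such dim genes toward 0, so these 2 ratios may be too small. Nrarp had 0.23 without replicate 4, and Hey1 -0.037 without replicate 2 and -0.41 without replicate 4. As a list, Notch targets were higher, with a median log2 ratio of 0.25 and 9 of 12 members above 0 (camera adjusted p = 0.00408, and adjusted p = 0.713 with an estimated correlation). Without replicate 3 the median was 0.17. Notch1 itself had 0.36 ± 0.24 and was higher on 2 of 4 arrays, with 0.064 without replicate 1. Whether its probe lies in the part that the transgene encodes is not given in the sources used here, so it checks nothing. In the wider Notch pathway list, which shares 3 genes with the targets, 0 of 29 members passed over all genes, and adjusted over the list alone 3 were higher and 3 lower. Among them, Numbl had 0.55 ± 0.12, Dtx3 0.32 ± 0.070 and Mfng, a sugar transferase that acts on Notch receptors, -0.79 ± 0.14. Over all genes Mfng passed with the array as a random block (adjusted p = 0.0222) and in separate channels without it (adjusted p = 0.0352). This list did not pass (camera adjusted p = 0.546).

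Adipocyte genes were lower as a list. Its median log2 ratio was -0.50, with 20 of 25 members below 0, 1 past the threshold over all genes (Acvr1c) and 10 lower when adjusted over the list alone (camera adjusted p = 4e-06, and adjusted p = 0.713 with an estimated correlation). Adrb3, the beta-3 adrenergic receptor, had -1.87 ± 0.23, and Adig, a gene of fat cells, had -1.04 ± 0.18. With the array as a random block 4 members passed over all genes, Acvr1c, Adrb3, Adig and the resistin gene Retn. In separate channels without the block, Acvr1c and Adig passed, while Adrb3 (adjusted p = 0.0715) and Retn (0.0711) did not. The hormone gene Adipoq had -0.95 ± 0.30 and was lower on 3 of 4 arrays. Lep, the leptin gene, had 0.19 ± 0.093 and Pparg, the master regulator of fat cell formation, 0.09 ± 0.10. Neither passed. Without replicate 2 they had 0.11 and 0.025, and Pparg had 0.20 without replicate 3. Both turned negative when arrays were median-centred instead of loess-normalised, a scaling that took the median of all genes from -0.006 to -0.33. The list's median was -0.33, -0.78, -0.98 and -0.044 on the arrays of replicates 1 to 4.

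Of the lists of lipid metabolism, 3 were lower at the preset correlation. The lipolysis list shares 8 of its 19 members with the adipocyte list, 3 of them among the 9 below, and is not a separate result for these. It had a median of -0.62, with 18 of 19 members below 0 and 9 lower when adjusted over the list alone (camera adjusted p = 5.58e-07). Its lowest p-values belonged to Adrb3, Slc27a1, a fatty acid transporter, at -1.54 ± 0.19, and Pck1, which makes phosphoenolpyruvate for glycerol synthesis, at -1.17 ± 0.20. Lipogenesis had a median of -0.57, with 24 of 26 below 0 and 2 lower over the list alone (adjusted p = 0.000221), namely Mogat1 at -1.51 ± 0.21 and Dgat1 at -1.08 ± 0.22, both enzymes of triglyceride synthesis. The lipogenesis median was 0.14, -1.54, -0.29 and -0.29 on the arrays of replicates 1 to 4, and it was -0.14 without replicate 2 and -0.91 without replicate 1. Gpam, which adds the first acyl chain, had -0.35 ± 0.099. Fatty acid oxidation had a median of -0.36, with 19 of 22 below 0 and 1 lower over the list alone (adjusted p = 0.0038), the peroxisomal enzyme Ehhadh at -1.30 ± 0.21. The oxidation median was 0.31, -1.14, -0.43 and -0.35 on the 4 arrays. Without replicate 2 it was -0.15 and the list did not pass (adjusted p = 0.163), and without replicate 1 it was -0.63. Pdk4, a kinase that holds back pyruvate oxidation, had -1.25 ± 0.40, with ratios of -0.09 to -2.62 on the arrays and -0.79 without replicate 2. Over all genes, 0 members of these lists passed in the ratio fit. With the array as a random block 5 did, namely Slc27a1 (adjusted p = 0.0168), Ehhadh (0.032), Mogat1 (0.0327), Adrb3 (0.039) and Dgat1 (0.0425). In separate channels without the block, Slc27a1 passed (adjusted p = 0.028) and the others did not (0.0561 to 0.0715). Each list had an adjusted p = 0.713 with an estimated correlation.

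The thermogenic list did not pass (camera adjusted p = 0.494), with 8 of 18 members above 0 and 1 lower over the list alone, Tbx1, which passed over all genes with the array as a random block (adjusted p = 0.0261). Tbx1 did not pass in separate channels without the block (adjusted p = 0.0505). The list passed without replicate 1 (median -0.29, adjusted p = 0.0375). Ucp1, the uncoupling protein of brown and beige fat, had -0.07 ± 0.80 and ratios of 2.42, -2.67, -0.46 and 0.45 on the 4 arrays. Prdm16 had 0.02 ± 0.11. The respiratory chain list (adjusted p = 0.0884) had 29 of 38 members below 0 and a median of -0.14, with 0.34 on the array of replicate 1 and -0.67 on that of replicate 2, and it passed without replicate 1 (median -0.30, adjusted p = 1.85e-06). Insulin and glucose genes had a median of -0.18, with 5 of 20 lower over the list alone (adjusted p = 0.0741), and cholesterol genes a median of -0.064 (adjusted p = 0.228). Without replicate 1 both passed, at medians of -0.17 (adjusted p = 0.011) and -0.12 (adjusted p = 0.0346). Leaving out each replicate in turn gave medians from -0.27 to -0.075 for insulin and glucose genes and from -0.12 to -0.021 for cholesterol genes. The insulin and glucose list also passed in separate channels with the array as a random block (adjusted p = 0.0391) and without it (adjusted p = 0.0302). Over all genes its members Insr and Pde3b passed with the array as a random block (adjusted p = 0.0208 and 0.0243). These list calls are at the preset correlation. With an estimated correlation 0 lists passed without replicate 1, the smallest adjusted p being 0.58, and over the 4 arrays these 4 lists had adjusted p = 0.713 to 0.869.

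Several lists of markers of other cell types passed at the preset correlation. All 14 endothelial genes were below 0, with a median of -0.26 and 7 lower over the list alone (camera adjusted p = 4e-06). The tight-junction gene Cldn5 had -1.21 ± 0.14, Robo4 -0.56 ± 0.11 and the VEGF receptor Kdr -0.37 ± 0.071, where 1 other Kdr probe pointed the other way. Cldn5 passed over all genes with the array as a random block (adjusted p = 0.0318), but not in separate channels without the block (adjusted p = 0.0595). All 15 skeletal muscle genes were below 0, with a median of -1.56 and 7 lower over the list alone (adjusted p = 5.58e-07). Tnnc2 had -2.61 ± 0.46, Myh4 -2.48 ± 0.54 and Mb -0.94 ± 0.19. The muscle median was -0.46, -1.74, -0.47 and -3.64 on the arrays of replicates 1 to 4, and it was -0.93 without replicate 4. Erythroid genes had a median of -0.61, with 5 of 5 below 0 and 3 lower over the list alone (adjusted p = 0.00103), Hbb-b1 at -0.88 ± 0.20, Hbb-bt at -0.80 ± 0.21 and Alas2 at -0.61 ± 0.14. B cell genes had a median of -0.28 (adjusted p = 0.00445), with Cd79b at -0.56 ± 0.18 and Ms4a1 at -0.48 ± 0.14. The B cell median was 0.24 on the array of replicate 2 and -0.48 without it, and without replicate 4 the list did not pass (median -0.26, adjusted p = 0.191). Mammary epithelium genes had a median of -0.43 (adjusted p = 0.0147), with array medians of -0.84, -1.36, 0.24 and -0.018. This list did not pass without replicate 1 (median -0.28, adjusted p = 0.114) or without replicate 2 (median -0.18, adjusted p = 0.242), and it had -0.74 without replicate 3. It did not pass in separate channels with the array as a random block (adjusted p = 0.467) or without it (adjusted p = 0.527). Krt5 had -0.94 ± 0.41 and ratios of -1.95, -1.80, -0.14 and 0.12 on the 4 arrays, with -0.61 without replicate 1. With an estimated correlation each of these 5 lists had an adjusted p = 0.713.

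Of the lists that were higher at the preset correlation, extracellular matrix had a median of 0.41, with 20 of 27 members above 0 (camera adjusted p = 0.000981). Its array medians were -0.39, 0.56, 0.19 and 1.29, and the list did not pass without replicate 4 (median 0.14, adjusted p = 0.191), while the median was 0.73 without replicate 1. Sparc, a collagen-binding matrix protein, had 1.11 ± 0.25, and the collagen genes Col6a2 and Col6a1 had 0.94 ± 0.21 and 0.90 ± 0.20. Cell cycle genes had a median of 0.16 with 21 of 23 above 0 (adjusted p = 0.00224), and Mcm4 had 0.46 ± 0.18, with 0.30 without replicate 2. Their array medians were -0.25, 0.54, 0.42 and 0.042. The list did not pass without replicate 2 (median 0.11, adjusted p = 0.163) or without replicate 3 (median 0.091, adjusted p = 0.0709), and it had 0.36 without replicate 1. Nerve genes had a median of 0.15 with 6 of 7 above 0 (adjusted p = 0.00612), which was 0.26 without replicate 1 and 0.42 without replicate 2. S100b, a marker of glia that adipocytes also express, had 1.35 ± 0.14 and was the 1 member higher over the list alone. Ngfr had 1.38 ± 0.45, with 3.03 on the array of replicate 2 and 0.83 without it. Inflammatory genes had a median of 0.16 with 12 of 16 above 0 (adjusted p = 0.01), and the chemokine gene Ccl8 had 1.39 ± 0.34. Array medians of the inflammatory list were -0.19, 0.29, 0.063 and 0.84. It did not pass without replicate 2 (median 0.20, adjusted p = 0.0959) or without replicate 4 (median 0.064, adjusted p = 0.283), and it had 0.29 without replicate 1. Granulocyte and mast cell genes had a median of 0.42 with 10 of 11 above 0 (adjusted p = 0.0121), and Mcpt4 had 0.71 ± 0.25, with 1.55 on the array of replicate 4 and 0.43 without it. Their array medians were -0.41, 0.35, 0.20 and 1.55. Without replicate 4 the median was 0.0023 and the list did not pass (adjusted p = 0.401), and without replicate 1 it was 0.71. With an estimated correlation each of these 5 lists also had an adjusted p = 0.713, and 0 of their members passed over all genes in the ratio fit. With the array as a random block S100b (adjusted p = 0.0236) and Col6a1 (adjusted p = 0.049) did. In separate channels without the block, S100b passed (adjusted p = 0.0467) and Col6a1 did not (adjusted p = 0.0711).

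In total 15 of 30 lists passed at the preset correlation, 9 lower and 6 higher. The correlation estimated between members of these lists ran from -0.094 for nerve to 0.77 for fatty acid oxidation, with 0.57 for adipocyte genes. For most it lay far above the preset 0.01, so the preset p-values rest on less shared variation than was estimated. With an estimated correlation 0 passed, the smallest adjusted p being 0.713, and with fry 0 passed in 1 direction, the smallest adjusted p being 0.167. The adjustment gave many lists the same 0.713. Among lists that passed at the preset correlation, camera's unadjusted p at the estimated one ran from 0.0525 for nerve to 0.451 for fatty acid oxidation. The simulated list shift of 0.5 was missed at this setting, so a miss there does not show that a list is unchanged. When the signs of the arrays of replicates 2, 3 and 4 were turned, a grouping that is not the real one, 17 lists passed at the preset correlation. Changes in either direction passed in fry for 6 lists, which were Notch targets, Notch pathway, adipocyte, nerve, ER stress, and p53 and senescence. In the ER stress list (camera adjusted p = 0.973), 2 of 12 members were higher over the list alone and 3 lower. The chaperone gene Hspa5 had 0.57 ± 0.093 and Atf4 0.53 ± 0.073, while Chac1, a target of ATF4, had -1.52 ± 0.15. These 3 and Asns passed over all genes with the array as a random block, at adjusted p-values of 0.0159 for Atf4, 0.0188 for Hspa5, 0.0068 for Chac1 and 0.047 for Asns. In separate channels without the block, these 3 passed and Asns did not (adjusted p = 0.079). In the p53 and senescence list (adjusted p = 0.651) the cell cycle inhibitor Cdkn2b had 0.51 ± 0.072.

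The remaining lists did not pass. Adjusted p-values were 0.0805 for smooth muscle, 0.099 for progenitor, 0.107 for epididymis with 1 measured gene, 0.184 for macrophage, 0.228 for immediate early, 0.546 for mesothelium, 0.881 for sex-linked with 1 measured gene, and 0.973 for T cell genes. T cell genes had a median of 0.0093 and a mean of -0.059, so that median and test differ in sign. Leaving out 1 replicate let 5 of these lists pass at the preset correlation. With an estimated correlation 0 lists passed, the smallest adjusted p being 0.58 without replicate 1 and 0.82 without replicate 4. Without replicate 1 these were macrophage (median 0.26, adjusted p = 0.000371) and progenitor (median 0.23, adjusted p = 0.00825). Without replicate 4 they were smooth muscle (median -0.30, adjusted p = 0.0105), epididymis (0.86, adjusted p = 0.014) and T cell genes, higher at a median of 0.24 (adjusted p = 0.0111).

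**Figure D2:**
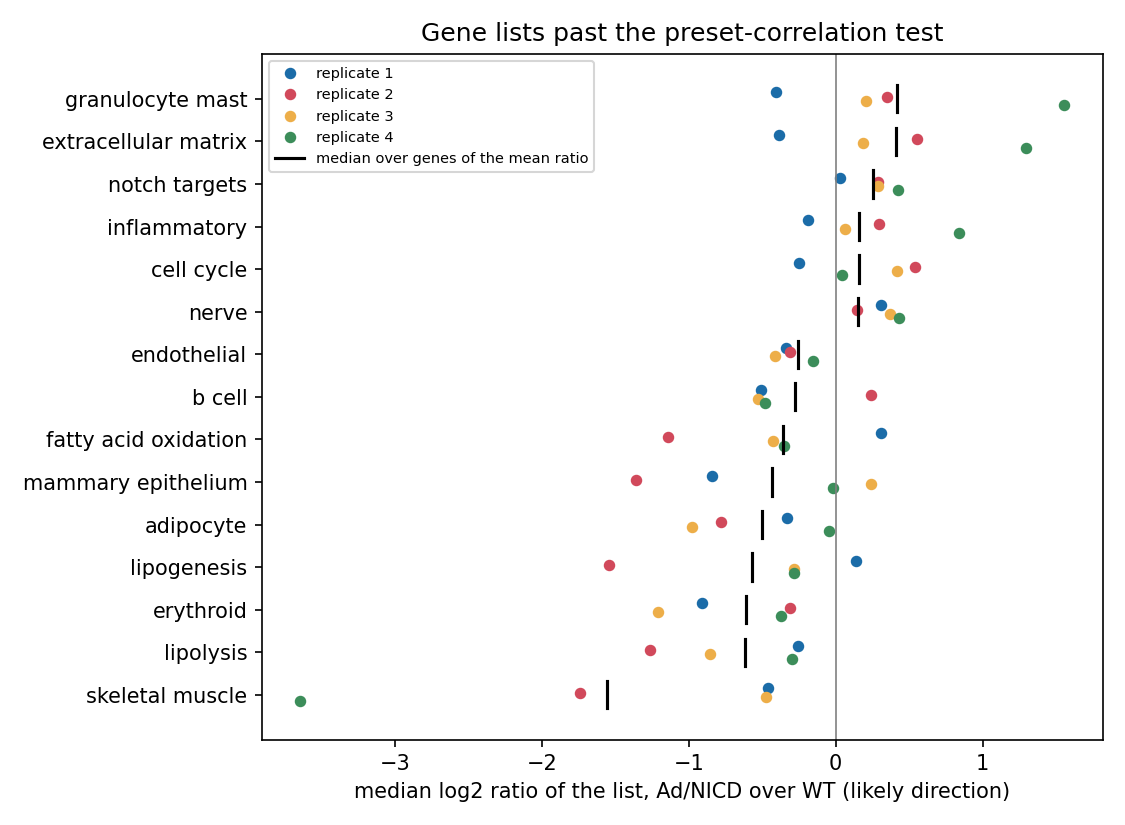
Median log2 ratio of Ad/NICD over WT (horizontal axis, likely direction) for the 15 gene lists that passed at the preset correlation, with 1 coloured point for each array and a black line at the median over genes of the mean ratio. Skeletal muscle genes reach -3.64 on the array of replicate 4, and endothelial genes stay between -0.16 and -0.42 on all 4 arrays.

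The 8 samples were also compared for their spread. The first principal component held 36.8% of the variance and set both samples of replicate 4 apart, at 52.7 for WT and 35.9 for Ad/NICD against values from -24.6 to -3.50 for the other 6. The second held 22.5% and separated the genotypes, and with them the dyes. XIST, the RNA that silences an X chromosome in female cells, had a log2 signal of 5.92 in WT and 5.90 in Ad/NICD of replicate 4, against 12.3 to 12.9 in the other 6 samples. Of 4 Y-linked genes, 3 were above background in WT and 4 in Ad/NICD of replicate 4, against 0 to 1 in the others. Median log2 signals of mammary epithelium genes were 6.34 and 6.65 in replicate 4, against 9.11 to 10.6 in the others. The muscle median was 11.95 in WT of replicate 4 and 9.04 in WT of replicate 2, against 6.80 to 7.94 in the other 6. The 2 samples of each pair lay on the same side for XIST. By XIST and the Y-linked genes, both samples of replicate 4 had the male pattern and the other 6 the female pattern. The labels give no sex. Correlations of log2 ratios between arrays, across genes, ran from -0.10 for replicates 1 and 4 to 0.50 for replicates 1 and 3.

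**Figure D3:**
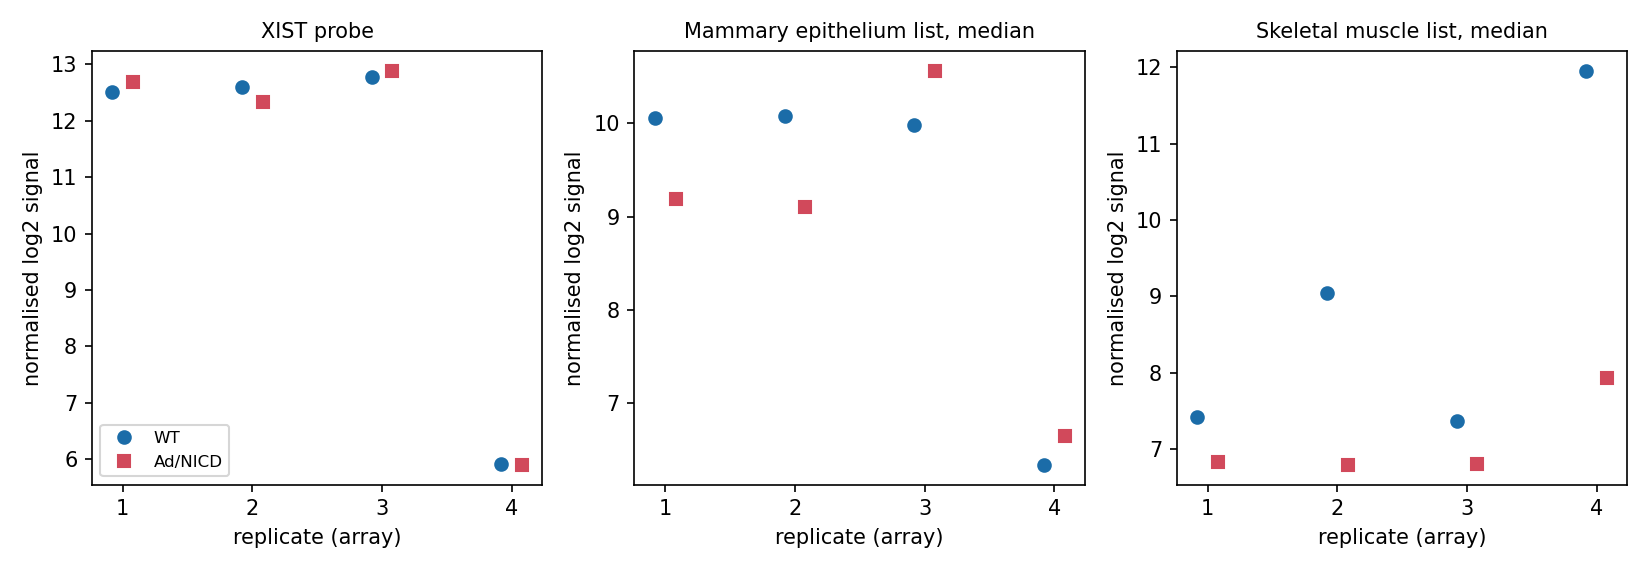
Normalised log2 signal (vertical axes) of the XIST probe, the mammary epithelium list and the skeletal muscle list in each sample, by replicate (horizontal axes), with circles for WT and squares for Ad/NICD. Both samples of replicate 4 are low for XIST, at 5.92 and 5.90, and WT of replicate 4 is highest for muscle, at 11.95.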

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

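The tests of muscle and adipocyte explanations were chosen after the results were seen, while the regroupings of samples were fixed before their counts were seen. Genotypes are named in the likely direction, and the dye tags would swap them throughout. Of 102 values tested, 3 had 1 array far from the other 3, and chance gives about 1 in 20. Adrb3 had -1.01 on the array of replicate 4 against -2.22 to -2.04 on the others. B cell genes had a median of 0.24 on the array of replicate 2 against -0.53 to -0.48. The epididymis list, which holds 1 measured gene, had -0.078 on the array of replicate 4 against 0.85 to 0.86. A signal outside the comparison came from Y-linked genes, with 4 above background in Ad/NICD and 3 in WT of replicate 4, against 0 to 1 in the other samples.

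With 8 sign patterns of the 4 arrays no share under 0.05 can be had. The real pattern gave 13 genes, 12 of 2-fold or more, and the highest other gave 0 for both counts, so 1 of 8 patterns reached each. For gene lists, 2 of 8 patterns gave at least 15, and the highest other gave 17. In the fit of separate channels without the array, the real split gave 257 genes, 1 of 35 splits gave as many, and the highest other gave 46. Those splits ignore the pairing of samples on arrays. Among the 8 splits that part all 4 pairs, the real one gave 257 and the highest other 0, and 8 are too few for a share under 0.05. The real split is also the split by dye.

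Skeletal muscle genes were lower in Ad/NICD, most on the array of replicate 4. A constant dye bias of the probes is argued against as the whole cause, since the list's median spanned 3.18 log2 units over the arrays. Random lists of like brightness spanned 0.333 at their 97.5th percentile. A constant bias added to another cause would leave this span as it is, so as a part of the fall it stays open. A candidate explanation is muscle tissue in some WT samples, or in Ad/NICD samples if the dye tags are right. A second list of 23 measured muscle genes had a median of -0.645, and in it Ttn had -1.58 and Pgam2 -1.67, with -4.05 and -4.24 on the array of replicate 4. On the arrays of replicates 1 and 3 the second list's median was -0.034 and -0.075, so there the first list has little support from it. An effect of genotype on muscle genes in the tissue stays open, as untested.

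Adipocyte genes were lower in Ad/NICD. A lower share of adipocytes as the whole cause would lower all members alike if they were expressed in adipocytes alone. Of 25 members, 12 departed from the list's median of their array, which argues against such an equal fall. A dye bias of single probes could add such departures, and so could expression in other cells. The count therefore does not exclude a lower share. Endothelial genes had a median of -0.259, below 0 on 4 of 4 arrays. This argues against a fall of adipocytes alone, with all other cells kept in proportion, which would raise it. A dye bias of the endothelial probes could also lower this median, and no array with swapped dyes exists to test that. Other medians were higher for extracellular matrix (0.41), granulocyte and mast cell (0.42) and nerve genes (0.15). They were lower for skeletal muscle (-1.56), erythroid (-0.61), mammary epithelium (-0.43) and B cell genes (-0.28). A shift in which cell types change unequally is thus not excluded. Dye bias cannot be told apart from genotype here: the adipocyte median varied by 0.935 log2 units over the arrays, and no array with swapped dyes exists to test its mean. An effect of Notch1 signalling on adipocyte genes stays open.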

How the results depend on the processing

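The filter from the arrays of replicates 2 to 4, the pairing in the authors' values and the estimated correlation without 1 replicate were chosen after seeing the data. The 13 genes kept their direction in 260 of 260 values over 20 alternatives and passed in 117. Each had the same sign on all arrays, so leaving out 1 could not turn it. Other tests on the same ratios could not either, so direction was tested only by the other processing steps. Sizes moved by over 1.5 times for Gdf5 (1.57 with the mean of its probes), Grb14 (0.69) and Zfp949 (0.52) with median centring, and Gdf7 (1.78 and 1.77 with processed signals, 1.76 in the authors' values). Lists that passed kept theirs in 285 of 285 over 19 alternatives and passed in 268. The cause of the changes below was not tested, except that leaving out an array removes a sample. Counts of genes changed, against 13, were 4 with processed signals without loess (3 higher, 1 lower) and 4 with loess (3 higher, 1 lower), 5 in the authors' values (3 higher, 2 lower), 0 with median centring, scaling between arrays, no dim filter, trend and robust eBayes, a plain test or an adjusted p under 0.01, and 32 at 0.1 (13 higher, 19 lower). At an unadjusted p under 0.05 scaling, trend and robust eBayes and the plain test gave 2889 to 3775, no dim filter 5092 of 36799 names, and median centring 9562, with all genes at a median of -0.33. Separate channels gave 257 (101 higher, 156 lower) without the replicate block and 495 (212 higher, 283 lower) with the array as a random block. Genes changed by 2-fold, against 12, were 4 and 4 with processed signals, 5 in the authors' values, 0 under those of the same settings that keep the threshold, 75 (18 higher, 57 lower) without the replicate block and 102 (24 higher, 78 lower) with the random block. Leaving out 1 replicate gave 0 to 43 genes, 0 to 42 of 2-fold and 11 to 20 lists. The random block changed the call of 2 lists, insulin and glucose and mammary epithelium. Lists fell from 15 to 0 with an estimated correlation, also without any 1 replicate, and with fry. The lowest pair correlation was 0.17, and 0.22 in the authors' values.

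Direction turned in these values, none past the threshold before. With median centring, Notch1 had -0.14, Lep -0.30, Pparg -0.32, Prdm16 -0.32, Mcm4 -0.013, E2f1 -0.11, Foxm1 -0.022, Tpsb2 -0.091 and Dtx3 -0.15, and p53 genes a median of -0.39 against 0.024. The test's direction turned, there too, for mesothelium at a median of -0.23 against -0.15 and thermogenic genes at -0.38 against -0.045. It turned for T cell genes at medians of 0.058 and 0.057 (processed, without and with loess), 0.022 (scaling), 0.0093 (no dim filter), 0.028 (mean of probes), 0.040 (every probe) and 0.045 (authors' values). For ER stress it did at 0.056 (processed with loess), -0.021 (no dim filter, every probe and trend) and 0.044 (authors' values), and for sex-linked genes at 0.061 (processed with loess), 0.0079 (mean of probes and every probe) and -0.037 (both separate-channel fits). Without 1 replicate the ranges were -0.077 to 0.12 for Prdm16, -0.89 to 0.80 for Ucp1, -0.071 to 0.10 for ER stress, -0.12 to 0.26 for macrophage, -0.30 to 0.032 for respiratory chain, -0.045 to 0.063 for p53, -0.11 to 0.034 for sex-linked, -0.14 to 0.24 for T cell (past the threshold without replicate 4, adjusted p = 0.0111) and -0.29 to 0.078 for thermogenic genes. Medians without 1 replicate also crossed 0 for mesothelium (-0.24 to 0.087) and progenitor genes (-0.0016 to 0.23), where the test's direction did not turn. Foreground close to background limits dim probes: with no filter 36799 gene names were tested.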

Other observations

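The gene families and the test in this part were chosen after values were seen. Major urinary protein genes, which encode pheromone carriers, were looked at because their values were low in Ad/NICD: 11 of 11 measured members were below 0, with a median of -2.34 and medians of -2.19, -3.27, -2.79 and -1.08 on the arrays of replicates 1 to 4. Over all genes 0 passed in the ratio fit, 9 with the array as a random block and 8 in separate channels without it. Mup1 had -3.34 ± 0.55 and Mup20 -3.27 ± 0.58. Several of these genes are near-identical copies whose probes can share signal, so such members are uncertain as separate genes. Of the enzymes of serine synthesis, Phgdh had -0.87 ± 0.068 and Psat1 -0.78 ± 0.072, both below 0 on 4 of 4 arrays, at adjusted p-values of 0.0538 and 0.0859 in limma, so neither passed in the ratio fit. With the array as a random block they had 0.00517 and 0.0168, and in separate channels without it 0.0124 and 0.0311, so both passed there. Psph, which makes serine in the last step, had 0.09 ± 0.14 and was above 0 on 3 of 4 arrays. Of 19 measured genes of serine synthesis and the amino acid response, 13 were below 0 and 6 above. Of 18 measured ligands of the BMP family and related genes, 12 were above 0 and 6 below, with a median of 0.09. Gdf5, Gdf7 and Bmp3 passed over all genes. Bmp4, at 0.25 ± 0.12, did not, nor did Bmp2 at -0.20 ± 0.10 or Bmp6 at -0.12 ± 0.12.

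Thermogenic genes went opposite ways on the arrays of replicates 1 and 2. A hypothesis is that the share of brown-like adipocytes differs between animals. Over the 8 samples, the Ucp1 level and the median level of the respiratory chain list had a Pearson r of 0.92 (exact permutation p = 0.000694) and a Spearman rho of 0.88 (exact permutation p = 0.00724), both 2-sided, with 1 relation computed. Leaving out the 2 samples farthest from the median Ucp1 level gave an r of 0.89 over 6 samples. Ucp1 was highest in WT of replicate 2, at a log2 signal of 15.2, and lowest in WT of replicate 1, at 12.2. By the dye tags these would be Ad/NICD samples of the same replicates. The samples of a pair share an array and are not fully independent, and the depot is not given, so differences in dissection, housing or regulation stay open beside the share of cells.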
